A study of Mus musculus with 14 samples.

How the data were processed

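Bulk RNA sequencing of whole mouse kidneys was compared between 3 groups: 4 control mice carrying the actin-rtTA transgene alone, 5 i-TERTci mice injected with the DMSO vehicle, and 5 i-TERTci mice injected with GSK2830371. All were given doxycycline. Per the labels, injections were daily and intraperitoneal and began at about day 15, once urinary protein had passed 10 mg/mL. No injection is recorded for the controls. Kidneys were taken at 30 days on doxycycline in the controls, at 29 to 38 days in the DMSO group and at 28 to 49 days in the GSK2830371 group. RNA integrity numbers were above 7 per the submitters' processing notes. Those notes name FastQC, Trimmomatic, STAR, DESeq2 and the mm10 build without versions. The read counter, the gene annotation and the strand setting are not given in the sources used here. The sex of the animals is not in the labels and was read from Xist and from the Y-linked gene Ddx3y.

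The deposited tables hold signal per gene. Their values were made by the authors as whole read counts divided by 1 size factor per library, although the tables are named as raw counts. Each of the 2 tables covers 9 libraries, with the same 4 controls in both, and its size factors were computed within that table. Every value was a whole multiple of its column's step within a tolerance of 0.001, so the whole reads could be recovered. The recovered control reads were identical in both tables for every shared gene (0 mismatches). There are 24221 genes in the vehicle table and 24164 in the inhibitor one. The 23682 genes in both were used, and the 539 and 482 genes in only 1 table were left out of the comparisons. The smallest gene total in either table is 10 reads. Gene coordinates, transcript lengths and gene classes came from GENCODE M21 (GRCm38), which matched 22780 genes (96.2%) and left 902 unmatched.

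The plan had assumed raw counts and edgeR. The deposited values were size-factor-normalized, and the main results were moved to limma 3.58.1 on log2 values of the recovered reads. The planned edgeR test could still be run on those reads, with edgeR 4.0.16, and became an added alternative. The reads of the 14 libraries were divided by median-of-ratios size factors computed over all 14, and log2 was taken after adding 1. The filterByExpr rule kept 18810 genes. All 14 libraries entered 1 linear fit by group with a mean-variance trend and robust variance moderation. Each of the 3 comparisons used limma's moderated test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Normalised read counts in the text are reads divided by the size factor, with the SD between mice. R 4.3.3, DESeq2 1.42.0 and Python 3.11.15 with matplotlib 3.10.9 were also used.

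Before the data were examined, 42 gene lists were fixed, of which 17 held cell-type markers and 25 held pathways. They hold 828 symbols, of which 815 were found, and 46 symbols are in more than 1 list. The cell-type lists cover podocytes, parietal epithelial cells, proximal tubule, loop of Henle, distal convoluted and connecting tubule, principal cells, intercalated cells, endothelium, mesangial and other mural cells with fibroblasts, macrophages and dendritic cells, T and natural killer cells, B and plasma cells, neutrophils, erythroid cells, adrenal gland, adipocytes and urothelium. The pathway lists cover injured tubule, extracellular matrix, inflammation and NF-kB, interferon response, complement and coagulation, cell cycle, p53 targets, DNA damage response, senescence and secretory factors, and the Wnt, TGF-beta and Notch pathways. Further pathway lists cover fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, glycolysis and hypoxia, ER stress, oxidative stress, immediate early and heat shock genes, mitochondrially encoded genes, telomerase and shelterin, the Ppm1d pathway, sex-linked genes, and genes biased to male or to female kidney. Lists with at least 5 measured genes were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with an estimated correlation and with fry.

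Named genes were chosen by a rule fixed with the lists. The rule names Tert and Ppm1d, and the 6 largest rises and 6 largest falls among changed genes. Those 12 needed at least 1 CPM (reads scaled to a common library size) in 1 group and no overlap between the groups' libraries, and predicted genes, clones and pseudogenes were left out. From each of 10 main lists it names the gene listed at the head and the pair with the smallest p. From every other list it names the gene with the smallest p. In a comparison with few changed genes it also names the 5 smallest p in each direction. A gene that falls outside this rule is given with the words that it was chosen after its values were seen.

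A disease score was computed for each i-TERTci library. It is the mean, over genes changed between all 10 i-TERTci libraries and the controls, of the log2 change in the direction of the i-TERTci libraries. All controls were Xist-positive, so these genes can include differences of sex and of library composition besides disease. GSK2830371 and DMSO were compared on this score with an exact two-sided permutation test over all 252 assignments. The overlap of both comparisons against the shared controls was set beside 20 simulations without an effect, independent lists, and controls divided between the comparisons.

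Recovered reads in genes were between 47.2 M and 64.6 M per library. At that depth the spread between mice, and not counting, limits the precision of most genes, and the p-values measure that spread. Lower bounds against an all-zero group use a floor of 3 counts in each library of that group and cover counting error only. The procedure was tested on simulated data built with the spread of these libraries. It recovered 23.6%, 27.2% and 33.7% of simulated 2-fold changes in the DMSO against control, GSK2830371 against control, and GSK2830371 against DMSO comparisons. It recovered 72.1%, 75.5% and 70.0% of 4-fold changes, with a mean of 3, 4 and 3.2 false calls. Each simulation changed 200 of 18810 genes. Far more genes changed against the controls, so the recovered shares may not apply there. A list with a simulated 2-fold change gave an adjusted p of 2.3e-15 with camera, with 0 of 40 other lists past the threshold. The simulated genes were drawn independently of each other, so this does not measure false list calls among correlated genes. Splits of the real libraries into other groups called a median of 14, 12 and 16 lists in the same 3 comparisons. In the comparisons with controls such splits could keep part of the difference between controls and i-TERTci libraries. Those medians therefore do not measure chance alone.

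The alternatives covered other scaling, filters, pseudocounts, tools and thresholds, days on doxycycline as a covariate or limited to 31, Xist as a covariate, libraries of 1 sex, a replicate block, protein-coding genes without an opposite-strand neighbour, the deposited values within 1 table, and leaving out each library. Other splits of the libraries into groups of the same sizes were drawn to see how often they gave as many calls.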

Results

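The data are bulk RNA sequencing profiles of whole kidneys from 14 mice. In i-TERTci mice, doxycycline switches on a catalytically inactive form of telomerase reverse transcriptase, and the mice develop collapsing glomerulopathy, a proteinuric disease of podocytes and the surrounding glomerular cells. There were 5 i-TERTci mice given the DMSO vehicle and 5 given GSK2830371, a selective inhibitor of the phosphatase WIP1, which the gene Ppm1d encodes. The controls were 4 single transgenic actin-rtTA mice. Recovered reads in genes ranged from 48.5 M to 64.6 M in the controls, from 47.2 M to 48.9 M in the DMSO group and from 48.4 M to 49.4 M in the GSK2830371 group. Values are normalised read counts with the SD between mice.

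The libraries differed in more than genotype. Reads in mitochondrial genes made up 14.4% to 24.2% of the control libraries, 4.95% to 9.52% of the DMSO libraries and 5.07% to 8.35% of the GSK2830371 libraries. The 10 most abundant genes took 21.7% to 36.6% of control reads and 11.3% to 18.1% of reads in the i-TERTci libraries. All 4 controls were Xist-positive. In the DMSO group 2 libraries were Xist-positive and 3 were Y-positive, and in the GSK2830371 group 3 were Xist-positive and 2 were Y-positive. The 3 Xist-positive GSK2830371 libraries were all at 49 days on doxycycline and the 2 Xist-positive DMSO libraries at 29 and 31 days, so a comparison of the treatments among Xist-positive libraries (n = 3 and 2) is also one of days. The libraries at 31 days or fewer were 2 with GSK2830371, both Y-positive, and 4 with DMSO, of which 2 were Xist-positive. The control labels also form a numbering block of their own, so genotype, label block and library composition cannot be separated in the comparisons with the controls. The leading principal component took 54.1% of the variance and parted the controls from all 10 i-TERTci libraries.

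**Figure D1:**
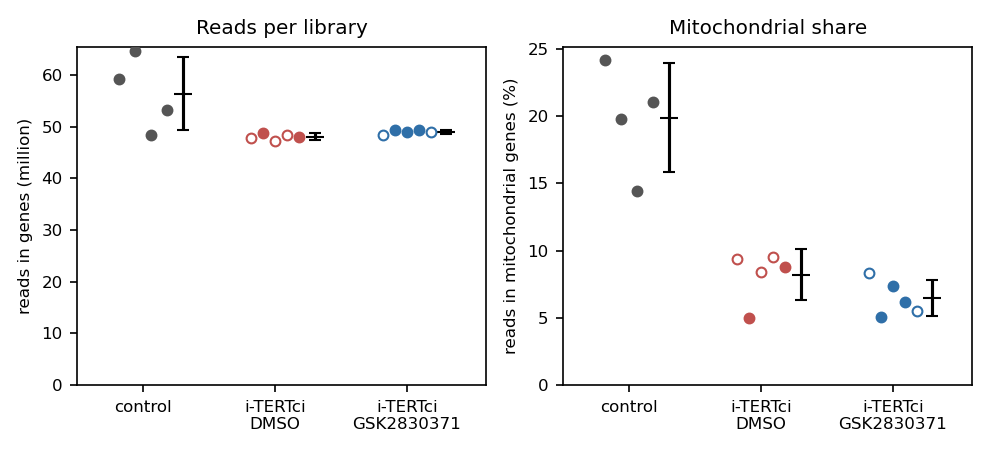
Reads in genes per library in M (left) and percent of reads in mitochondrial genes (right) for the control, DMSO and GSK2830371 groups. Each point is 1 library, open points are Y-positive libraries, and bars give the mean and SD. Control libraries lie between 14.4% and 24.2% mitochondrial reads and all i-TERTci libraries below 9.52%.

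The comparison of DMSO-treated i-TERTci kidneys with controls asked what the disease changes in the kidney. Tert, the reverse transcriptase that the transgene encodes, rose from 146 ± 27.5 (SD, n = 4) to 1535 ± 778 (SD, n = 5), a log2 change of 3.24 (SE 0.60, limma adjusted p = 0.00062). The largest rises among changed genes were in the neutrophil genes S100a8 and Ngp, and the largest falls in the serum corticosteroid carrier Serpina6 and the brain cytoplasmic RNA Bc1. Lcn2, the injury marker NGAL, rose from 479 ± 300 (SD, n = 4) to 43048 ± 30090 (SD, n = 5), a log2 change of 6.50 (SE 0.70, adjusted p = 1.23e-05). Cdkn1a, the cell cycle inhibitor p21 and a p53 target, rose from 890 ± 204 (SD, n = 4) to 7617 ± 3742 (SD, n = 5), a log2 change of 2.89 (SE 0.55, adjusted p = 0.00074). Ppm1d fell from 901 ± 29.3 (SD, n = 4) to 549 ± 42.9 (SD, n = 5), a log2 change of -0.72 (SE 0.16, adjusted p = 0.0020). Tert (ENSMUSG00000021611) lies on chromosome 13 from 73626911 to 73649843 and Ppm1d (ENSMUSG00000020525) on chromosome 11 from 85311244 to 85347066 (GRCm38). The values do not part transgenic from native Tert, since the data used here are gene totals.

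**Figure D2:**
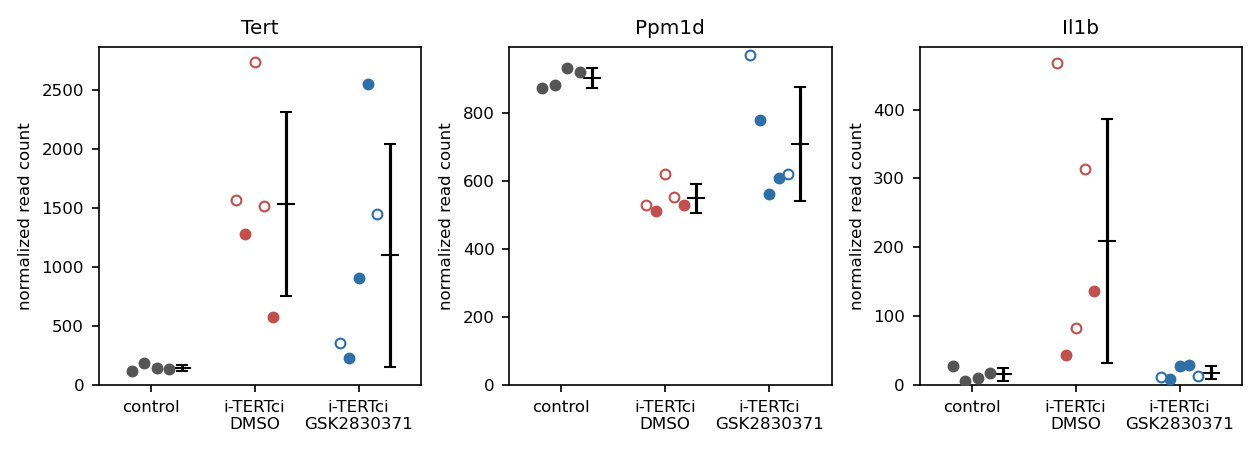
Normalised read counts of Tert, Ppm1d and Il1b per library in the control, DMSO and GSK2830371 groups. Points are libraries, open points are Y-positive libraries, and bars give the mean and SD. Tert averaged 146 in controls, 1535 with DMSO and 1097 with GSK2830371, and Il1b averaged 15.4, 209 and 18.1.

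S100a8, which encodes a neutrophil calcium-binding protein, rose by 8.37 (log2, adjusted p = 0.00049) and the neutrophil granule gene Ngp by 8.14 (adjusted p = 0.0013). Chil3, made by activated macrophages and neutrophils, rose by 7.53 (adjusted p = 3.15e-05), the neutrophil-attracting chemokine Cxcl1 by 7.22 (adjusted p = 1.45e-05) and the neutrophil surface gene Cd177 by 7.01 (adjusted p = 0.0010). Saa1, an acute-phase protein, averaged 0.464 in controls and 1177 ± 1619 (SD, n = 5) with DMSO (adjusted p = 0.00067). Serpina6 fell by 9.39 (adjusted p = 2.59e-05). Bc1 fell by 9.37 (adjusted p = 4.20e-08), from 1516 ± 351 (SD, n = 4) to 1.75 ± 1.74 (SD, n = 5). The mitochondrial tRNA mt-Tm was at least 69.1-fold lower, with 0 reads in every DMSO library (adjusted p = 5.97e-09). The adipocyte serine protease gene Cfd fell by 7.02 (adjusted p = 0.0172), Prss35 fell by 6.67 (adjusted p = 0.00061) and Ccdc170 fell by 6.61 (adjusted p = 0.0046).

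Of 18810 genes tested, 9079 (48.3%) changed, 4742 upward and 4337 downward, and 2719 and 2726 of them by at least 2-fold. Among Xist-positive libraries alone 6124 genes passed, and edgeR and DESeq2 called 8892 and 9534. For each list, counts adjusted over the list alone are given where they differ from the counts over all genes. No list kept its call when camera estimated the correlation between genes, and the adjusted p with an estimated correlation stands beside each. With fry 17 lists passed, 13 of them among the lists called here.

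The neutrophil, inflammation, complement, macrophage and senescence lists rose. In the neutrophil list 13 of 14 genes rose and 0 fell (14 adjusted over the list alone), with a mean log2 change of 5.47 (adjusted p = 3.22e-05, and adjusted p = 0.663 with an estimated correlation). Retnlg, a neutrophil resistin-like gene, rose by 6.96. In the inflammation and NF-kB list 21 of 29 rose and 0 fell, with a mean of 2.20 (adjusted p = 3.22e-05, and adjusted p = 0.581 with an estimated correlation). Ccl2, a monocyte-attracting chemokine, rose by 2.01 (adjusted p = 0.0278). Its call was lost without control replicate 3 (1.61, adjusted p = 0.0903), control replicate 4 (1.78, adjusted p = 0.0803) or DMSO replicate 4 (1.49, adjusted p = 0.0645). In the complement and coagulation list 13 of 19 rose and 0 fell (14 adjusted over the list alone), with a mean of 2.06 (adjusted p = 0.000661, and adjusted p = 0.581 with an estimated correlation), and Cfb, a factor of the alternative pathway, rose by 1.98. In the macrophage and dendritic cell list 13 of 27 rose and 2 fell (16 and 2 adjusted over the list alone), with a mean of 1.17 (adjusted p = 0.00508, and adjusted p = 0.807 with an estimated correlation). The osteopontin gene Spp1, also a member of the injured tubule list, rose by 3.27 and the Fc receptor gene Fcgr3 by 2.40. The macrophage marker Cd68 did not pass (1.04, adjusted p = 0.107). In the senescence and secretory list 14 of 20 rose and 1 fell, with a mean of 1.97 (adjusted p = 0.00516, and adjusted p = 0.658 with an estimated correlation).

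Of 5 nephron segment lists 4 fell. In the proximal tubule list 15 of 30 fell and 2 rose, with a mean of -1.08 (adjusted p = 0.000833, and adjusted p = 0.729 with an estimated correlation). The phosphate transporter gene Slc34a1 fell by 2.14 (adjusted p = 0.0020), from 361366 ± 118501 (SD, n = 4) to 89690 ± 47371 (SD, n = 5). The organic anion transporter gene Slc22a8 fell by 2.77 and the amino acid transporter gene Slc7a8 fell by 2.65. In the intercalated cell list 10 of 12 fell and 0 rose, with a mean of -1.92 (adjusted p = 0.000152, and adjusted p = 0.658 with an estimated correlation), and the ammonia transporter gene Rhbg fell by 3.63. In the principal cell list 8 of 11 fell and 0 rose, with a mean of -1.56 (adjusted p = 0.000511, and adjusted p = 0.581 with an estimated correlation), and the transcription factor gene Gata3 fell by 2.62. In the distal convoluted and connecting tubule list 7 of 11 fell and 0 rose, with a mean of -1.25 (adjusted p = 0.0122, and adjusted p = 0.674 with an estimated correlation), and Calb1, a calcium-binding protein gene, fell by 1.99. The loop of Henle list did not pass, with 3 of 12 up and 2 down (adjusted p = 0.834), although Ppp1r1a fell by 2.15.

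Glomerular lists did not pass. In the podocyte list 5 of 28 genes rose and 10 fell (mean -0.23, adjusted p = 0.524). Nphs1, which encodes the slit diaphragm protein nephrin, was 1773 ± 219 (SD, n = 4) in controls and 2636 ± 1364 (SD, n = 5) with DMSO and did not pass (0.43, adjusted p = 0.414). Thsd7a, a podocyte membrane protein gene, rose by 1.25 (adjusted p = 6.08e-05) and Clic3 fell by 3.19 (adjusted p = 0.00016). In the parietal epithelial cell list 4 of 12 rose and 3 fell (mean 0.44, adjusted p = 0.741). Cd44, a marker of activated parietal cells, rose by 2.10 (adjusted p = 0.00033), Cp, the ceruloplasmin gene, rose by 2.49 (adjusted p = 0.00024), and the nephron development gene Pax2 fell by 2.51 (adjusted p = 1.80e-06). The mesangial, mural and fibroblast list had 0 up and 4 of 18 down (0 and 3 adjusted over the list alone, adjusted p = 0.188), and the endothelial list 2 up and 8 of 18 down (3 and 8 adjusted over the list alone, adjusted p = 0.0849). Ehd3, a gene of glomerular endothelium, fell by 1.29 (adjusted p = 0.00018). Without DMSO replicate 1 the endothelial list passed (-0.51, adjusted p = 0.0442).

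The injured tubule, p53 target, ER stress and extracellular matrix lists rose and the Wnt list fell. In the injured tubule list 16 of 24 rose and 3 fell (17 and 3 adjusted over the list alone), with a mean of 1.90 (adjusted p = 0.000511, and adjusted p = 0.658 with an estimated correlation). Besides Lcn2, Dcdc2a rose by 2.43. Havcr1, the tubular injury marker Kim-1, fell by 2.76 (adjusted p = 0.0095), from 17545 ± 3910 (SD, n = 4) in the controls to 4245 ± 4315 (SD, n = 5). In the p53 target list 15 of 34 rose and 3 fell, with a mean of 0.83 (adjusted p = 0.0115, and adjusted p = 0.658 with an estimated correlation), among them Rps27l (1.73) and the apoptosome gene Apaf1 (1.69). In the ER stress list 12 of 26 rose and 1 fell (13 and 1 adjusted over the list alone), with a mean of 0.91 (adjusted p = 0.00516, and adjusted p = 0.729 with an estimated correlation), and the disulfide isomerase gene Pdia6 rose by 1.88. In the extracellular matrix list 13 of 35 rose and 2 fell (11 and 2 adjusted over the list alone), with a mean of 0.83 (adjusted p = 0.0416, and adjusted p = 0.814 with an estimated correlation). That call was lost without control replicate 3 (0.66, adjusted p = 0.163) or DMSO replicate 2 (0.61, adjusted p = 0.137). The protease inhibitor gene Timp1 rose by 5.39 and Tgfbi by 2.44, and the collagen gene Col1a1 did not pass (0.43, adjusted p = 0.690). In the Wnt list 14 of 26 fell and 6 rose (15 and 6 adjusted over the list alone), with a mean of -0.56 (adjusted p = 0.013, and adjusted p = 0.674 with an estimated correlation), and the transcription factor gene Lef1 fell by 2.66.

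Among the remaining pathway lists none passed. In the immediate early and heat shock list 11 of 21 rose and 1 fell (adjusted p = 0.0545), and Atf3 rose by 4.21. It passed without control replicate 2 (1.03, adjusted p = 0.038), DMSO replicate 3 (1.05, adjusted p = 0.0477) or DMSO replicate 5 (1.20, adjusted p = 0.0139). In the interferon list 3 of 30 rose and 6 fell (adjusted p = 0.460), with Ifi44 at -2.02. In the cell cycle list 3 of 38 rose and 4 fell (adjusted p = 0.706). Pcna, the DNA polymerase clamp, rose by 1.48 and Kif23 by 1.64, and the proliferation marker Mki67 did not pass (-0.25, adjusted p = 0.752). In the DNA damage list 4 of 25 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.990), and in the Ppm1d pathway list 3 of 14 rose and 3 fell (adjusted p = 0.817). The histone gene H2ax, a member of both, fell by 1.5. In the fatty acid oxidation list 7 of 28 rose and 3 fell (adjusted p = 0.644). Its regulator Ppara rose by 1.27 (adjusted p = 0.0071), Eci1 rose by 1.15 and Hadha fell by 0.96. Up and down counts were 5 and 10 of 34 for oxidative phosphorylation (adjusted p = 0.95), 1 and 6 of 21 for cholesterol synthesis (adjusted p = 0.188), 5 and 6 of 22 for glycolysis and hypoxia (adjusted p = 0.817), and 8 and 3 of 23 for oxidative stress (7 and 3 adjusted over the list alone, adjusted p = 0.386). They were 5 and 3 of 20 for TGF-beta (4 and 3 adjusted over the list alone, adjusted p = 0.741), 1 and 6 of 14 for Notch (adjusted p = 0.134), and 3 and 4 of 13 for telomerase and shelterin (adjusted p = 0.918). Within these lists Etfb (-3.01), Mvk (-1.19), the catalase gene Cat (-1.18), Hes1 (-0.93) and the shelterin gene Acd (-1.54) fell, while Hk2 rose by 2.59 and Tgfbr1 by 1.32. The oxidative phosphorylation list had a mean of -0.06 and a median of 0.18 with a downward test, and the telomerase list a mean of 0.17 and a median of -0.0015 with a downward test.

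The lists of other cell types, of sex and of the mitochondrial genome did not pass either, although single members did. In the mitochondrially encoded list 4 of 13 rose and 7 fell (adjusted p = 0.95). The gene mt-Nd6, which lies on the strand opposite to most mitochondrial genes, rose from 344 ± 219 (SD, n = 4) to 9430 ± 2343 (SD, n = 5), a log2 change of 4.93 (adjusted p = 3.48e-07). The male-biased list had 4 of 9 up and 0 down (5 adjusted over the list alone, adjusted p = 0.0759), with Cyp4b1 up by 2.79, and it passed without DMSO replicate 2 (3.0, adjusted p = 0.0219) or DMSO replicate 5 (2.95, adjusted p = 0.0219). The female-biased list had 3 of 5 down (adjusted p = 0.155), and the prolactin receptor gene Prlr fell by 3.58. The sex-linked list had 1 of 5 up (0 adjusted over the list alone, adjusted p = 0.386). Ddx3y averaged at least 661-fold more than the all-zero controls (adjusted p = 0.0455), a call lost when any 1 control or DMSO replicate 1, 3 or 4 was left out (adjusted p from 0.0614 to 0.108). T and natural killer cell genes had 0 of 18 up and 4 down (1 adjusted over the list alone, adjusted p = 0.134), with the T cell receptor gene Trac down to 45.2 from 189, and the list passed without DMSO replicate 5 (-1.21, adjusted p = 0.0176). Adipocyte genes had 3 of 8 down (adjusted p = 0.0851), with the lipase gene Lpl at -2.10, and that list passed without control replicate 2 (-3.50, adjusted p = 0.0189). B and plasma cell genes had 1 of 15 up, which was Sdc1 (2.03), and 1 down (1 and 0 adjusted over the list alone, adjusted p = 0.719). Erythroid genes had 2 of 8 down (adjusted p = 0.134), including Slc4a1, also an intercalated cell gene, which fell by 4.87. Urothelial genes had 1 of 8 up, which was Krt20 (6.71), and 5 down (adjusted p = 0.160). Of 3 adrenal genes, too few for a list test, the corticotropin receptor gene Mc2r rose by 1.96 (adjusted p = 0.0101).

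Some calls of DMSO against control ended within 1 sex or with another model. Among Xist-positive libraries alone the ER stress list (0.537, adjusted p = 0.0868), Ccl2 (2.0, adjusted p = 0.0808), Cfd (-6.26, adjusted p = 0.191), Prss35 (-5.91, adjusted p = 0.0595), Ccdc170 (-4.05, adjusted p = 0.137), Ppara (1.26, adjusted p = 0.069), Lpl (-2.78, adjusted p = 0.0525) and Mc2r (0.757, adjusted p = 0.329) did not pass. With Xist as a covariate Ccl2 (1.70, adjusted p = 0.10), Cfd (-6.35, adjusted p = 0.0544) and Mc2r (1.57, adjusted p = 0.0538) did not pass, and with fry the extracellular matrix list did not (adjusted p = 0.0886). Calls gained were Cd68 with DESeq2 (1.27, adjusted p = 0.0196), with voom (adjusted p = 0.016) and at 31 days or fewer (adjusted p = 0.0193), and, among Xist-positive libraries alone, the adipocyte, endothelial and erythroid lists, all lower (adjusted p = 0.0442, 0.0161 and 0.0174). The adipocyte list also passed at 31 days or fewer (adjusted p = 0.0063), the T and natural killer cell list with a replicate block (adjusted p = 0.0276), the immediate early list with fry, no filter or a replicate block (adjusted p from 0.0151 to 0.0285), the male-biased list with no filter or a replicate block (adjusted p = 0.0459 and 0.049), and the Notch, endothelial and female-biased lists with fry (adjusted p = 0.0362, 0.0191 and 0.0191). For Cfd, DESeq2 gave no adjusted p (-7.6) and voom did not call it (adjusted p = 0.19).

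**Figure D3:**
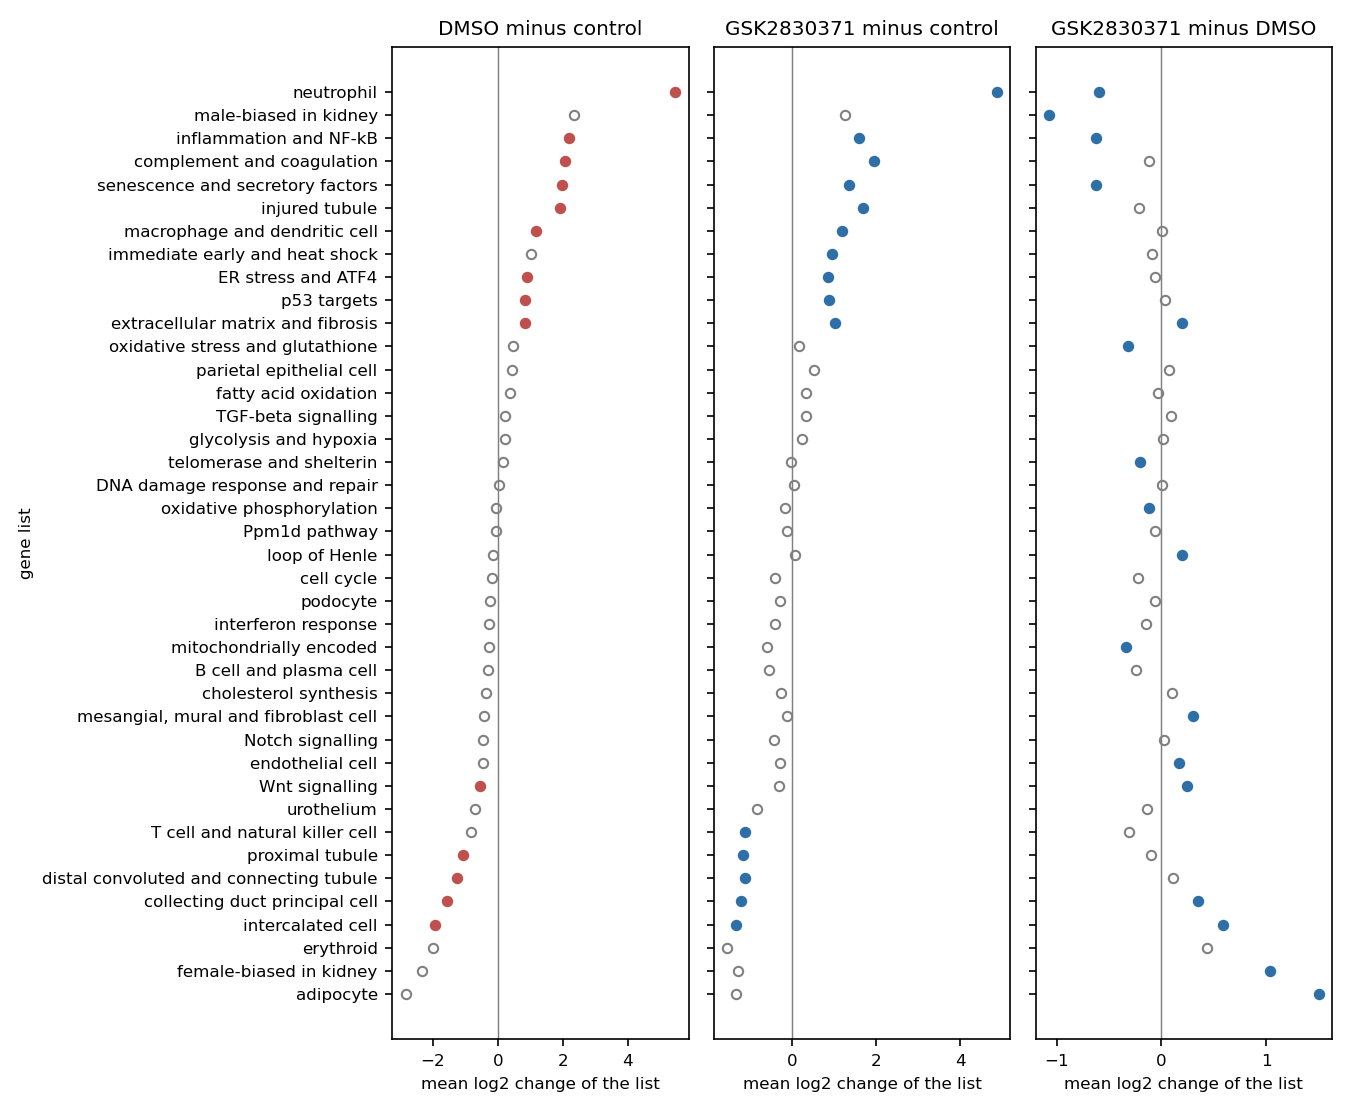
Mean log2 change of each gene list in the 3 comparisons, with filled points for lists past an adjusted p of 0.05 at a preset correlation of 0.01 and open points for the others; the sex-linked list is left out for scale. The neutrophil list lies at 5.47 and 4.87 against controls and at -0.60 between GSK2830371 and DMSO. With an estimated correlation 0 lists passed in each comparison.

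The comparison of GSK2830371-treated i-TERTci kidneys with controls asked how far the treated kidneys differed from healthy ones. Lcn2 again rose, to 52813 ± 31887 (SD, n = 5) from 479 ± 300 (SD, n = 4), a log2 change of 6.76 (SE 0.70, adjusted p = 9.39e-06), and Cdkn1a rose to 9959 ± 6294 (SD, n = 5), a change of 3.26 (SE 0.55, adjusted p = 0.00034). Tert rose to 1097 ± 943 (SD, n = 5), a change of 2.41 (SE 0.60, adjusted p = 0.0048). Ppm1d was 707 ± 168 (SD, n = 5) and did not pass (-0.38, adjusted p = 0.0659), but passed without GSK2830371 replicate 1 (-0.50, adjusted p = 0.0136). The neutrophil genes Ngp (7.68), S100a8 (7.47), Chil3 (7.06) and Cd177 (6.53) rose, as did Mmp7, a matrix protease gene of injured tubule, by 6.58 (adjusted p = 0.00035). Among named genes the largest falls were in Bc1 (-9.57), Serpina6 (-7.77), the potassium channel gene Kcng1 (-6.63) and Apol10b (-6.32), and mt-Tm and mt-Ti were at least 71.4-fold and 28.5-fold lower, with 0 reads in each GSK2830371 library.

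Of 18810 genes, 8716 (46.3%) changed, 4568 upward and 4148 downward, and 2594 and 2560 of them by at least 2-fold. Among Xist-positive libraries alone 7808 genes passed, and edgeR and DESeq2 called 8496 and 9118. The list tests called 10 lists up and 5 down, 4 of which depended on single libraries and are given apart. With an estimated correlation 0 lists passed, with adjusted p = 0.854 for every list called. With fry 16 lists passed, 14 of them among those called. Upward lists were neutrophil (13 of 14 up), complement and coagulation (13 of 19), injured tubule (14 of 24, 3 down), macrophage and dendritic cell (15 of 27, 1 down), inflammation (15 of 29, 1 down), p53 targets (15 of 34, 3 down), extracellular matrix (13 of 35, 2 down or 1 adjusted over the list alone) and ER stress (10 of 26). Their adjusted p ran from 0.000388 to 0.00517. Downward lists were proximal tubule (15 of 30 down, 2 up, adjusted p = 0.00267), principal cell (8 of 11 down, adjusted p = 0.00401) and intercalated cell (8 of 12 down, adjusted p = 0.00401). The podocyte list (7 of 28 up, 10 down, or 8 and 10 adjusted over the list alone, adjusted p = 0.420) did not pass. The mesangial (-0.11 and 0.15), oxidative phosphorylation (-0.17 and 0.14) and telomerase (-0.03 and 0.12) lists had means and medians of opposite sign, with downward tests.

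Within these lists Nphs1 did not pass (0.09, adjusted p = 0.871), Thsd7a rose by 1.38 and Clic3 fell by 3.29. Cd44 rose by 1.99, Cp by 2.77, the macrophage mannose receptor gene Mrc1 by 2.72, Spp1 by 3.47, Timp1 by 5.06 and the NF-kB inhibitor gene Tnfaip3 by 2.03. Pmaip1, a pro-apoptotic p53 target, rose by 2.69, the class I histocompatibility gene H2-K1 by 2.57, and the immediate early gene Fos by 2.82. The transporter genes Slc34a1 and Slc22a8 fell (-2.17 and -3.07), as did the inositol oxygenase gene Miox (-3.47), the distal tubule gene Pvalb (-5.28), Rhbg (-2.55) and Havcr1 (-2.42, adjusted p = 0.0198). The Notch target gene Hes1 (-1.18), H2ax (-1.82), Acd (-1.63) and the insulin-like growth factor binding gene Igfbp5 (-2.19) fell. Cd68 (1.06, adjusted p = 0.102), Col1a1 (1.28, adjusted p = 0.221), Ccl2 (1.39, adjusted p = 0.118) and Mki67 (-0.78, adjusted p = 0.30) did not pass, although Cd68 passed without GSK2830371 replicate 3 (1.44, adjusted p = 0.0178). The mitochondrial gene mt-Nd6 rose by 4.89 and the male-biased gene Cyp4b1 by 2.35, and the female-biased gene Prlr fell by 2.55.

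Single libraries decided the calls of 5 further lists and of Lpl in this comparison. In the senescence list 9 of 20 rose and 2 fell (adjusted p = 0.0499), a call lost without control replicate 3 or 4 or GSK2830371 replicate 2 or 4 (adjusted p = 0.0936, 0.0673, 0.0541 and 0.0929). In the immediate early list 10 of 21 rose and 1 fell (adjusted p = 0.0401), a call lost without control replicate 1 or 3 or GSK2830371 replicate 1 or 2 (adjusted p = 0.0541, 0.0562, 0.0700 and 0.0695). In the distal convoluted and connecting tubule list 5 of 11 fell and 1 rose (adjusted p = 0.0442), a call lost without control replicate 3 or 4 or GSK2830371 replicate 2 (adjusted p = 0.0588, 0.0679 and 0.0695). In the T and natural killer cell list 5 of 18 fell and 0 rose (4 adjusted over the list alone, adjusted p = 0.0374), a call lost without control replicate 1 or GSK2830371 replicate 1 or 3 (adjusted p = 0.134, 0.053 and 0.0573). With an estimated correlation each of these 4 had an adjusted p of 0.854. The Wnt list had 6 of 26 up and 12 down (6 and 13 adjusted over the list alone, adjusted p = 0.0653) and passed without control replicate 3 or GSK2830371 replicate 5 (adjusted p = 0.0473 and 0.0496). The lipase gene Lpl fell by 2.0 and lost its call without control replicate 1 (-1.80, adjusted p = 0.0516), with DESeq2 (-1.45, adjusted p = 0.0835), with edgeR (-1.44, adjusted p = 0.0801) and among Xist-positive libraries alone (-1.81, adjusted p = 0.111), where Havcr1 (-1.84, adjusted p = 0.0592) did not pass either. With days on doxycycline as a covariate the ER stress list did not pass (0.696, adjusted p = 0.0588), nor did the 4 lists called above (adjusted p from 0.0785 to 0.115), which also did not pass with Xist as a covariate (adjusted p from 0.052 to 0.0644). The T and natural killer cell list did not pass with fry (adjusted p = 0.127) or at 31 days or fewer (adjusted p = 0.0661), nor the senescence list with TMM scaling (adjusted p = 0.0558). For Pvalb DESeq2 gave no adjusted p (-4.07). Calls gained were Ppm1d with upper quartile scaling (adjusted p = 0.0444), with voom (adjusted p = 0.00933) and among Xist-positive libraries alone (-0.47, adjusted p = 0.0378), Cd68 with DESeq2 (adjusted p = 0.0164), Ccl2 at 31 days or fewer (adjusted p = 0.0285), Mki67 with voom (adjusted p = 0.0396), and the Wnt list with fry, a replicate block or Xist-positive libraries alone (adjusted p = 0.0193, 0.0376 and 0.0314). At 31 days or fewer the male-biased list passed upward (3.05, adjusted p = 0.0113) and the adipocyte list downward (-2.37, adjusted p = 0.0223). The telomerase list passed with fry (adjusted p = 0.0382). Ddx3y passed with DESeq2 (adjusted p = 8.32e-18), with Xist (adjusted p = 0.0262) or days (adjusted p = 0.0218) as a covariate, and at 31 days or fewer (adjusted p = 0.0193).

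Both groups of i-TERTci kidneys shared most of their changes against the controls. Upward calls overlapped in 3971 genes, where 1152 would be shared by independent lists, downward calls in 3600 (956 independent), and 0 genes were called in opposite directions. The changes correlated at r = 0.958 across genes, which are not independent replicates. The controls enter both comparisons, and simulations without an effect gave r = 0.556 and 0 shared calls, with a covariance of 0.0964 against 1.62 observed. The simulated genes were drawn independently of each other and few calls can arise without an effect. The 0 shared calls are therefore no measure of chance overlap among correlated genes. With the controls divided 2 and 2 between the comparisons the covariance was 1.55 to 1.58, r was 0.881 to 0.915, and 1841 to 2087 genes rose and 1636 to 1874 fell in both. Every division kept the differences of sex, label block and library composition between controls and i-TERTci libraries.

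The comparison of GSK2830371 with DMSO in i-TERTci mice asked what WIP1 inhibition changes in the diseased kidney. With limma 0 of 18810 genes passed, 800 had an unadjusted p under 0.05 where chance gives 940.5, and the lowest adjusted p was 0.994. Il1b, which encodes the inflammatory cytokine interleukin-1 beta, had the smallest p among the inflammation genes. It was 209 ± 178 (SD, n = 5) with DMSO, 18.1 ± 9.70 (SD, n = 5) with GSK2830371 and 15.4 ± 9.30 (SD, n = 4) in controls. Its log2 difference was -3.13 (95% interval -4.38 to -1.88, limma adjusted p = 0.994), and all 5 GSK2830371 libraries lay below all 5 DMSO libraries, in Xist-positive and Y-positive libraries alike. DESeq2 called this gene alone (-3.53, adjusted p = 1.48e-05), and edgeR called 0 genes with 871 at an unadjusted p under 0.05. Adjusted over the list alone, Il1b passed in the inflammation list (adjusted p = 0.00208) and in the senescence list (adjusted p = 0.00144). Against controls Il1b rose with DMSO (3.38, adjusted p = 0.00047) and did not pass with GSK2830371 (0.25, adjusted p = 0.770). The gene overlaps another gene on the opposite strand.

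The inflammation list was lower with GSK2830371 (mean -0.62, adjusted p = 1.27e-06, and adjusted p = 0.463 with an estimated correlation), with 0 of 29 members past the test over all genes and 1, Il1b, adjusted over the list alone. Its NF-kB subunit gene Nfkb2 was at -0.54 and lay below every DMSO library in 4 of 5 libraries. The intercalated cell list was higher (mean 0.59, adjusted p = 8.91e-05, and adjusted p = 0.463 with an estimated correlation), with 0 of 12 past over all genes and 3 adjusted over the list alone. These were the proton pump subunit gene Atp6v0d2 (1540 ± 373 against 868 ± 331, SD, n = 5 each), Rhbg (48.8 ± 12.5 against 24.9 ± 12.8) and the water channel gene Aqp6 (3313 ± 1781 against 1413 ± 636), the last of these chosen after its values were seen. Control means were 2235, 286 and 4244. The mesangial, mural and fibroblast list was also higher (mean 0.31, adjusted p = 8.91e-05, and adjusted p = 0.463 with an estimated correlation), with 0 of 18 past, and the pericyte proteoglycan gene Cspg4 at 0.75. These 3 lists kept their calls when any 1 library was left out, but none kept it with fry (adjusted p = 0.612, 0.697 and 0.697). The inflammation mean was -0.403 without GSK2830371 replicate 3 and the intercalated mean 0.376 without DMSO replicate 4. At 31 days or fewer on doxycycline the inflammation list did not pass (-0.433, adjusted p = 0.0777). Among Xist-positive libraries alone the inflammation list passed (-0.601, adjusted p = 8.60e-07), while the intercalated list was at 0.0352 with a downward test (adjusted p = 0.985) and the mesangial list at 0.0125 (adjusted p = 0.531).

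A further 14 lists passed at the preset correlation, with 0 members past over all genes, and each lost its call when a single library was left out. With an estimated correlation their adjusted p ran from 0.463 to 0.904. Higher with GSK2830371 were the principal cell list (0.35, adjusted p = 0.00342), lost without GSK2830371 replicate 4 (adjusted p = 0.0658), and the Wnt list (0.25, adjusted p = 0.0213), lost without DMSO replicate 1 or GSK2830371 replicate 4 or 5 (0.0695 to 0.336). The endothelial list (0.17, adjusted p = 0.0252) was lost without DMSO replicate 2, 4 or 5 or GSK2830371 replicate 1 or 3 (0.0502 to 0.177), and the adipocyte list (1.5, adjusted p = 0.0252) without DMSO replicate 2 or 5 or GSK2830371 replicate 4 (0.0703 to 0.608), the library in which the adipokine gene Adipoq reached 1313. The extracellular matrix list (0.20, adjusted p = 0.0303) was lost without DMSO replicate 1, 4 or 5 or GSK2830371 replicate 1, 2, 4 or 5 (0.0502 to 0.589), and the loop of Henle list (0.20, adjusted p = 0.0491) without any 1 library but DMSO replicate 1 and GSK2830371 replicate 2 (0.0502 to 0.504). The female-biased list (1.04, adjusted p = 0.0241) was lost without DMSO replicate 1, 3 or 4 or GSK2830371 replicate 3 or 4 (0.0526 to 0.106). The mean moved by over 1.5 times in the Wnt list without DMSO replicate 1 (0.147), in the adipocyte list without GSK2830371 replicate 4 (0.736) and in the endothelial list without DMSO replicate 4 (0.0661). In the extracellular matrix list it was 0.0386 and 0.419 without DMSO replicates 1 and 2 and 0.0491 and 0.419 without GSK2830371 replicates 2 and 3, and in the loop of Henle list 0.401 and 0.0574 without DMSO replicates 1 and 4 and 0.315 and 0.127 without GSK2830371 replicates 2 and 3.

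Lower with GSK2830371 among these 14 were the oxidative stress list (-0.32, adjusted p = 0.00342), lost without GSK2830371 replicate 5 (0.0588), and the senescence list (-0.63, adjusted p = 0.00405, 1 member adjusted over the list alone), lost without DMSO replicate 1 or GSK2830371 replicate 3 (0.0567 and 0.0754). The mitochondrially encoded list (-0.34, adjusted p = 0.00916) was lost without DMSO replicate 1 or 4 or GSK2830371 replicate 2, 4 or 5 (0.0544 to 0.0742), and the oxidative phosphorylation list (-0.12, adjusted p = 0.0213) without DMSO replicate 1 or 4 or GSK2830371 replicate 2 or 5 (0.141 to 0.819). The male-biased list (-1.07, adjusted p = 0.0285) was lost without DMSO replicate 1, 3 or 4 or GSK2830371 replicate 2, 3 or 4 (0.0692 to 0.447). The neutrophil list (-0.60, adjusted p = 0.0426) was lost without DMSO replicate 1, 3 or 4 or GSK2830371 replicate 2, 4 or 5 (0.0619 to 0.908), and the telomerase list (-0.21, adjusted p = 0.0426) without any 1 library but DMSO replicates 2 and 5 and GSK2830371 replicate 3 (0.0502 to 0.157). The neutrophil mean was -0.179, -1.13, -0.193 and -0.992 without DMSO replicates 1, 2, 3 and 5 and -1.17, -0.255, -1.07 and 0.0595 without GSK2830371 replicates 1 to 4, the last with its sign turned. The male-biased mean was -0.578, -1.74, -0.291 and -1.69 without DMSO replicates 1, 2, 4 and 5 and -1.75 and -0.674 without GSK2830371 replicates 1 and 3. The oxidative phosphorylation mean was 0.0146, -0.184 and -0.0703 without DMSO replicates 1, 3 and 4 and -0.186, -0.0571 and -0.0239 without GSK2830371 replicates 1, 2 and 5. The mitochondrially encoded mean was -0.214 and -0.512 without DMSO replicates 1 and 2, and the oxidative stress mean -0.52 without DMSO replicate 5.

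Of the 17 lists called, 0 kept direction and call with fry, 3 at 31 days or fewer (extracellular matrix, intercalated and mesangial), 3 among Xist-positive libraries alone (inflammation, adipocyte and endothelial), 11 with days as a covariate and 13 with Xist as a covariate. With days as a covariate the neutrophil mean was 0.104 (adjusted p = 0.865). At 31 days or fewer, where both GSK2830371 libraries were Y-positive against 2 of 4 with DMSO, the neutrophil (0.606, adjusted p = 0.229) and male-biased (1.5, adjusted p = 0.01) lists turned upward and the female-biased list had a downward test (0.15, adjusted p = 0.988). Among Xist-positive libraries alone, 3 at 49 days against 2 at 29 and 31 days, the neutrophil (0.596), male-biased (0.302) and oxidative phosphorylation lists (0.133, adjusted p = 0.00357) turned upward, the mitochondrially encoded mean was 0.0229 (adjusted p = 0.985), the extracellular matrix list turned downward (-0.185), and the Wnt (0.0347), oxidative stress (-0.0498) and telomerase (-0.0163) lists had tests against their means.

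The lists closest to the target and the disease did not pass the test. The p53 target list averaged 0.04 (adjusted p = 0.735), the Ppm1d pathway list -0.06 (adjusted p = 0.735) and the podocyte list -0.06 (adjusted p = 0.735). Cdkn1a was at 0.38 (95% interval -0.73 to 1.48), Nphs1 at -0.34 (-1.18 to 0.51), Ppm1d at 0.34 (0.01 to 0.66), Slc34a1 at -0.04 (-1.0 to 0.92) and Havcr1 at 0.34 (-1.22 to 1.90). The stress cytokine gene Gdf15, a p53 target, was 436 ± 287 (SD, n = 5) against 2016 ± 2322 (SD, n = 5), with 6100 in DMSO replicate 4 and 476 to 1549 in the other DMSO libraries, and Sesn1, another p53 target, was 2572 ± 2230 (SD, n = 5) against 912 ± 269 (SD, n = 5), a log2 difference of 1.19 that was 0.772 without GSK2830371 replicate 1 (6421). The lipid droplet gene Plin2 (-1.53), the heme oxygenase gene Hmox1 (-1.83) and the stress gene Ddit4 (1.42) also did not pass. Hmox1 was 52520 in DMSO replicate 4 and 949 to 3870 in the other DMSO libraries, and without that library its difference was -0.905. Besides Il1b, the smallest p belonged to Cnnm3 (0.65), Zscan2 (0.77), Fgd5 (0.59), Zkscan14 (0.83) and Muc20 (0.91) among higher genes and to 2300002M23Rik (-2.07), Sertad1 (-0.87), Ubash3b (-1.06) and Rpia (-0.99) among lower ones, each with adjusted p = 0.994. The proximal tubule (-0.10 and -0.03, upward test), injured tubule (-0.21 and 0.02, downward test) and glycolysis lists (0.01 and -0.0047, upward test) had a mean, median and test that differed in sign and did not pass. The proximal tubule list passed upward without DMSO replicate 4 or GSK2830371 replicate 2 (0.13 in each case, adjusted p = 0.0298 and 0.0113), and the injured tubule list downward without DMSO replicate 5 or GSK2830371 replicate 2 (-0.40 and -0.36, adjusted p = 0.0166 and 0.0275).

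Other lists that did not pass over all 10 libraries gained a call at the preset correlation in part of them. The interferon list (-0.142, adjusted p = 0.0738) passed downward without DMSO replicate 1, 3 or 4 or GSK2830371 replicate 2, 4 or 5 (adjusted p from 0.000129 to 0.0451), the cell cycle list (-0.224, adjusted p = 0.0738) without DMSO replicate 1 or GSK2830371 replicate 1 or 4 (2.12e-06 to 0.00372), and the T and natural killer cell list (-0.309, adjusted p = 0.0572) without DMSO replicate 1, 3 or 4 or GSK2830371 replicate 5 (0.00238 to 0.0257). Upward calls appeared for the distal convoluted and connecting tubule list without DMSO replicate 1 or 5 or GSK2830371 replicate 2 (0.00198 to 0.0278), the parietal list without DMSO replicate 2 or GSK2830371 replicate 3 (0.0282 and 0.0149), and the cholesterol list without DMSO replicate 2 or 4 (0.0339 and 0.00808). Without DMSO replicate 1 the B and plasma cell list passed downward (0.00174) and the erythroid (0.0278) and fatty acid oxidation (0.0278) lists upward, and without DMSO replicate 4 the macrophage list passed downward (0.0256). Among Xist-positive libraries alone the T and natural killer cell (-1.41), interferon (-0.685), macrophage (-0.704), B and plasma cell (-0.711), cell cycle (-0.599) and DNA damage (-0.268) lists passed downward and the erythroid (1.64), fatty acid oxidation (0.405) and ER stress (0.377) lists upward (adjusted p from 2.74e-16 to 0.0128). At 31 days or fewer the parietal, proximal tubule, cholesterol, glycolysis and sex-linked lists passed upward and the interferon list downward (adjusted p from 0.00844 to 0.0411). With days as a covariate the macrophage list passed upward (0.33, adjusted p = 0.014), and with Xist as a covariate the interferon (adjusted p = 0.0022) and T and natural killer cell (adjusted p = 0.00711) lists passed downward.

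The median 95% half-width per gene was 0.55 on the log2 scale. A simulated 2-fold change was recovered in 33.7% of genes and a 4-fold change in 70.0%. Differences of 2-fold or less were therefore mostly not detectable with 5 mice in each group, and some 4-fold differences were missed.

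The disease score summed these values for each mouse. Over 10049 genes changed between all i-TERTci libraries and the controls, it averaged 1.41 ± 0.148 (SD, n = 5) with DMSO and 1.36 ± 0.192 (SD, n = 5) with GSK2830371. Sex may enter the score, since all controls were Xist-positive. Y-positive libraries (3 DMSO and 2 GSK2830371) scored 1.38 to 1.54 and Xist-positive ones (2 and 3) scored 1.14 to 1.56. The difference of -0.045 did not pass (exact two-sided permutation test over 252 assignments, p = 0.714). It was -0.0408 for the 5241 genes higher in disease (exact permutation p = 0.635) and -0.0495 for the 4808 lower ones (exact permutation p = 0.738). The direction turned at 31 days or fewer (0.0705, exact permutation p = 0.667), without GSK2830371 replicate 4 (0.0147, exact permutation p = 0.881) and among Xist-positive libraries alone (0.0144). Among the latter 2 genes passed between GSK2830371 and DMSO, Gm10036 (3.98) and Gm6724 (5.83), each with adjusted p = 0.00232. Over all libraries this pair of predicted genes, chosen after their values were seen, was at 0.01 and 0.64. With Y-positive libraries alone, 3 and 2 in number, 0 genes passed, with 704 at an unadjusted p under 0.05.

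**Figure D4:**
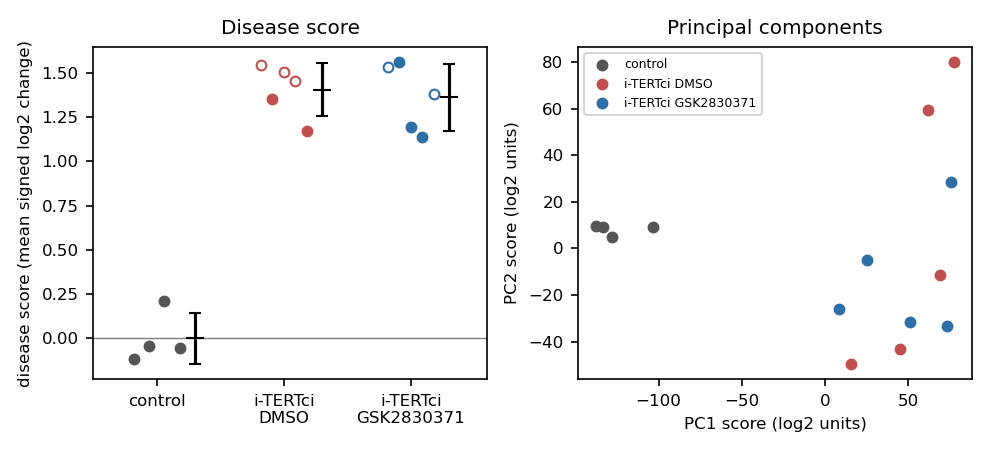
Disease score of each library (left, open points are Y-positive libraries, bars give the mean and SD) and the leading principal components of all 14 libraries, which took 54.1% and 10.4% of the variance (right). DMSO scores lie between 1.17 and 1.54 and GSK2830371 scores between 1.14 and 1.56.

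Tent5a, which encodes a poly(A) polymerase and was chosen after its values were seen, rose in every i-TERTci library. Tent5a (ENSMUSG00000032265, chromosome 9 from 85320439 to 85327348) was 467 on average in controls, with a range of 421 to 534, and 30040 ± 7742 in the 10 i-TERTci libraries, with a range of 21830 to 44110. That is a log2 change of 5.97, the 41st largest in size among 18810 genes. Bc1 and Tent5a parted the controls from every i-TERTci library whatever the treatment.

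**Figure D5:**
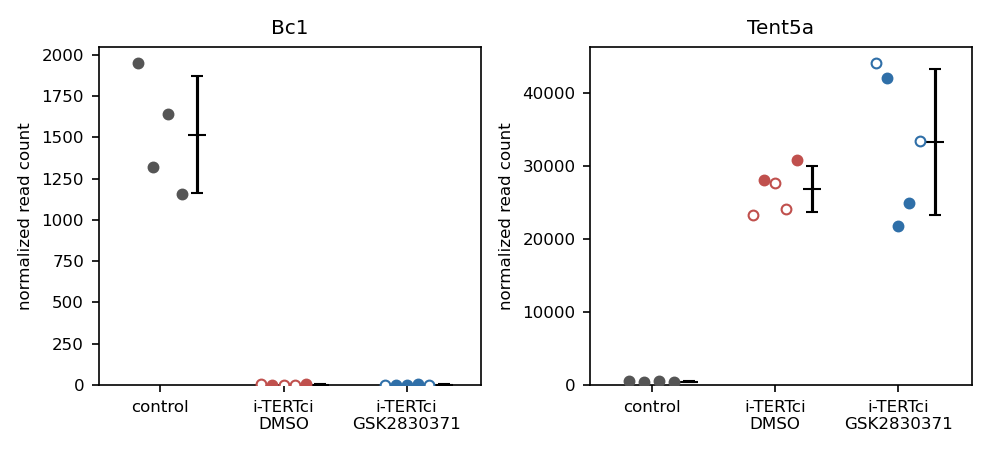
Normalised read counts of Bc1 and Tent5a per library on linear axes, by group. Points are libraries, open points are Y-positive, and bars give the mean and SD. Bc1 averaged 1516 in controls and reached at most 4.33 in an i-TERTci library, and Tent5a lay between 421 and 534 in controls and between 21830 and 44110 in i-TERTci libraries.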

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

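The tests in this part were written down before their results were seen, with these exceptions. The division of the i-TERTci libraries by sex and the tests of strand on the antisense and pseudogene features alone were chosen afterwards. For the test of the inhibitor's effect between the sexes no prediction was written. Each pattern was noticed in the data before it was tested.

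Features annotated as antisense or processed pseudogene were higher in the i-TERTci libraries than in the controls, with a median log2 change of 0.79 over 1508 features (interval 0.69 to 0.91) against -0.0073 for protein-coding genes. Reading 1 set of libraries without strand could give this. It is argued against for the 642 such features that overlap no listed gene on the opposite strand, which were still at 0.992 (interval 0.824 to 1.08). These 642 were not divided by class. Antisense features were at 0.39 (interval 0.155 to 0.503) and processed pseudogenes at 1.09 (interval 1 to 1.17). Few of the 642 may be antisense, so the question is not settled for antisense features. For features of both classes nested in another gene, reading without strand cannot be told apart. Those on the opposite strand (1.26, interval 0.947 to 1.63) and on the same strand (1.06, interval 0.408 to 1.31) differed by 0.202 with a wide interval (-0.148 to 1.0). Over nested features of every class that difference was 0.0179 (interval -0.202 to 0.251), and antisense features took 0.145% to 0.166% of reads in controls and 0.130% to 0.179% in i-TERTci libraries. On the minority strand of the mitochondrial genome mt-Nd6 (4.91), mt-Te (3.08) and mt-Tp (2.84) rose, as this explanation would have it, and mt-Tq did not (-0.698). On the majority strand mt-Co3 (2.30), mt-Tw (2.19), mt-Co2 (1.80), mt-Atp6 (0.958), mt-Nd4l (0.409) and mt-Nd3 (0.334) were higher too. The other genes of that strand had negative changes, so the rise was not confined to the minority strand. A trend with GC content is argued against as the whole cause, since the median was still 0.737 (interval 0.655 to 0.836) after that trend was removed. A library preparation that differed between the sets may account for the pattern, since features under 200 nt other than Bc1 and the mitochondrial genes were also higher, by a median of 1.22 (interval 0.731 to 1.43, 51 of 65 higher), but Bc1 and mt-Tm moved the other way. Whether the controls were prepared apart is not recorded. Label block and genotype coincide in these samples, so disease itself stays open as an untested explanation.

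Tent5a rose from 467 to 30040 ± 7742 (SD, n = 10), a log2 change of 5.97, with no overlap between the controls and any i-TERTci library. The sex of the animals is argued against, since the change was 5.952 (95% interval 5.553 to 6.351) among Xist-positive libraries alone. An effect of the locus, such as an integrated transgene or a strain interval, is a candidate explanation, since the 7 genes tested within 1 Mb had a median absolute change of 1.36, at percentile 95.6 of 18199 such windows (median 0.63, 95th percentile 1.33). The margin over that percentile is narrow, and 3 of the 7 neighbours averaged under 4 reads in the controls. A response of Tent5a to the disease stays open and was not tested apart from genotype.

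No gene passed with limma between GSK2830371 and DMSO, and 800 had an unadjusted p under 0.05. Chance cannot be excluded for these 800, since 58 of 100 splits of the 10 libraries gave as many, and the highest other gave 4101 with 467 genes past the threshold. That split set DMSO replicates 1, 3 and 4 with GSK2830371 replicates 1 and 2, which points to a structure of the samples. These 5 have the highest disease scores of the 10 (1.45 to 1.56, against 1.14 to 1.38 in the others), and 4 of the 5 are Y-positive. The division into 5 Xist-positive and 5 Y-positive libraries gave 82 genes past the threshold and 2243 unadjusted. Sex might hide an effect, but with Xist as a covariate 0 genes passed while 26.2% of simulated 2-fold changes were recovered, and with days on doxycycline as a covariate 0 genes passed while 5.6% were recovered, so neither explanation can be told apart from a small effect of the inhibitor. In the GSK2830371 group the 3 Xist-positive libraries are the 3 at 49 days and the 2 Y-positive ones are at 28 and 31 days, so sex and days cannot be told apart there. The difference of the inhibitor's effect between the sexes was tested as well, and 0 of 17825 genes passed, with 444 at an unadjusted p under 0.05 where chance gives 891, but that test carries the days with it.

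Against the controls, chance is argued against for the gene counts, within the limit of 100 splits. Each other split mixed controls with i-TERTci libraries, so this cannot part genotype from sex, label block or library composition. Only the real split of 100 gave 9079 genes for DMSO (highest other 7125) and only the real split of 100 gave 8716 for GSK2830371 (highest other 6498), so the count was 1 in each, and the highest other splits set all 4 controls with a single i-TERTci library. As many lists were called in 58 of 100 splits for DMSO against control (14, highest other 27) and in 32 for GSK2830371 against control (15, highest other 22). In both comparisons with controls, other splits could keep part of the difference between controls and i-TERTci libraries. Their list counts therefore do not measure chance alone, and whether chance gives as many lists there stays undecided. Between GSK2830371 and DMSO chance cannot be excluded for the number of lists. As many were called in 44 of 100 splits (17, highest other 23, and 9 without GSK2830371 replicate 4 or 11 without replicate 5).

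A library lay far from the others of its group in 22 of 453 groups of values, where a nominal rate of 1 in 20 gives 22.6. Most of these groups are named genes, many picked for small p or for no overlap between groups, and genes are not independent. The nominal rate is therefore not a fair expectation, and the nearness of both numbers is not read as a result. The mitochondrial share of DMSO replicate 2 was 4.948%, and the other DMSO libraries had 8.44% to 9.52%. In control replicate 1, Cfb was 73.68 and Ppara 542.1, both low. Control replicate 2 was high in Saa1 at 1.855 and low in Cfd at 22.26 and Adipoq at 0. Control replicate 3 was low in mt-Tm at 96.27, Ehd3 at 3472 and Mki67 at 185.5, and high in Apaf1 at 187.5. Control replicate 4 was low in Cdkn1a at 586.2, Atf3 at 47.08 and Sertad1 at 592.1, and high in Npnt at 19410. In the DMSO group, Eci1 was high in replicate 1 at 12560, Prss35 high in replicate 2 at 14.67, Hsd3b1 and Pdk1 low in replicate 4 at 10.57 and 1007, and Cdkn1a low in replicate 5 at 1756. In the GSK2830371 group, Pax2 was low in replicate 1 at 876.9, Trac low in replicate 3 at 15.77 and Atp6v0d2 low in replicate 4 at 911.

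Among genes listed in only 1 table, which the comparisons did not use, Krt6a averaged 22.8 reads in the DMSO libraries and 0 in the controls, and Elovl3 averaged 22.2 reads in the GSK2830371 libraries and 0.75 in the controls. Each mean rests on 1 library, with 113 reads of Krt6a in DMSO replicate 1 and 111 of Elovl3 in GSK2830371 replicate 4, and without it the means were 0.25 and 0.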

How the results depend on the processing

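Some alternatives were chosen after seeing the data: TMM scaling (the planned RLE scaling being already the main one), edgeR on recovered reads, the pseudocounts, libraries of 1 sex, protein-coding genes, the deposited values within 1 table, and leave-one-out for the overlap. Of the named genes, 58 of 71, 60 of 72 and 70 of 71 never changed their call in DMSO against control, GSK2830371 against control and GSK2830371 against DMSO, and 19, 22 and 8 of 41 lists did not. No named gene that passed in either setting reversed its direction under any alternative run. Between GSK2830371 and DMSO 0 genes passed in the main fit, so a turn of sign was hardly counted there. The 70 of 71 are genes that stayed uncalled. Depth limits little at 47.2 M reads or more, and the spread between mice limits the rest.

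With an estimated correlation 0 lists passed in each of the 3 comparisons. With fry 0 passed between GSK2830371 and DMSO, where 17 passed at the preset correlation. Against controls fry passed 17 lists for DMSO and 16 for GSK2830371. Of these, 13 and 14 were also called at the preset correlation. The cause of these differences was not tested. Against controls, a 1.5-fold minimum left 3350 genes for DMSO and 2911 for GSK2830371, and an adjusted p under 0.01 left 5757 for GSK2830371, as stricter thresholds must. Protein-coding genes without an opposite-strand neighbour gave 4875 and 4666, with 10431 genes tested. Between GSK2830371 and DMSO, DESeq2 called 1 gene and Xist-positive libraries 2, and libraries at 31 days or fewer gave 10 lists; the cause was not tested. Dividing the controls gave 3477 to 3950 shared calls from fewer controls, against 7571.

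The test of a list called in either setting reversed its direction only between GSK2830371 and DMSO, in 14 lists, and the cause was not tested. The GSK2830371 libraries at 31 days or fewer are 2 Y-positive ones, and the Xist-positive ones are the 3 at 49 days, so both settings change sex and days together. At 31 days or fewer the reversed lists were neutrophil 0.606, sex-linked 3.17, male-biased 1.5 and female-biased 0.15. In Xist-positive libraries they were intercalated cell 0.0352, macrophage -0.704, neutrophil 0.596, extracellular matrix -0.185, DNA damage -0.268, Wnt 0.0347, fatty acid oxidation 0.405, oxidative phosphorylation 0.133, ER stress 0.377, oxidative stress -0.0498, telomerase -0.0163 and male-biased 0.302. Without 1 replicate the range was -0.265 (without DMSO replicate 4) to 0.202 for macrophage, -0.141 to 0.169 (without DMSO replicate 1) for fatty acid oxidation, and -0.186 to 0.0146 (without DMSO replicate 1) for oxidative phosphorylation. In called lists the mean also turned sign under a test that kept its direction, to 0.104 with days as a covariate and 0.0595 without GSK2830371 replicate 4 for neutrophil and to 0.0229 in Xist-positive libraries for mitochondrially encoded. The means of lists not called turned sign in 8, 3 and 23 lists of DMSO against control, GSK2830371 against control and GSK2830371 against DMSO.

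Without 1 replicate, changed genes ranged from 7645 to 9108 for DMSO against control, 7254 to 8625 for GSK2830371 against control and 0 to 0 between the treatments. Lists ranged from 13 to 17, 12 to 16 and 9 (without GSK2830371 replicate 4, and 11 without replicate 5) to 16, the disease score difference from -0.114 to 0.0147 and the overlap from 6242 to 7572. The labels do not say whether replicate numbers pair the samples. Correlations of equal numbers across groups ran from -0.0605 to 0.335, and 6 of 14 libraries matched their own number best. A weak pairing is therefore not excluded. With a replicate block 9589, 9248 and 0 genes and 17, 16 and 18 lists passed.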

Other observations

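The tests in this part were written down before their results were seen, and the genes of the mitochondrial genome and the level of Kap were looked at after the main comparisons.

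The mitochondrial genome did not change as a block between controls and i-TERTci kidneys. The ribosomal RNAs mt-Rnr1 and mt-Rnr2 were at -2.99 and -3.05 on the log2 scale and the complex I subunit genes mt-Nd1, mt-Nd2 and mt-Nd4 at -2.33, -2.83 and -2.80. The abundant mt-Co1, mt-Nd5 and mt-Cytb also fell (-0.781, -1.59 and -1.77), from control means of 2112000, 1382000 and 2666000. In the other direction, mt-Nd6 was at 4.91 (344 reads in controls and 9597 in i-TERTci libraries). Also higher were mt-Co2 at 1.80 (1218 and 4398) and mt-Co3 at 2.30 (743 and 3785). These 3 had very few reads beside the abundant genes, and why was not tested, so their changes may not reflect transcript levels. The tRNAs mt-Tm, mt-Ti and mt-Td had 0 reads in all i-TERTci libraries. Antisense features rose in 313 cases and fell in 165 of 814 in DMSO against control, and processed pseudogenes rose in 368 and fell in 59 of 694.

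Kap, an androgen-regulated gene of the proximal tubule, was 786900 to 1461000 in the 4 Xist-positive controls, 21920 to 49060 in the 5 Xist-positive i-TERTci libraries, and 145200 to 1089000 in the 5 Y-positive i-TERTci libraries. These values were chosen after they were seen and no explanation was tested.

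The disease score might follow the level of the transgene or the time on doxycycline. Across the 10 i-TERTci libraries Pearson's r with log2 Tert was -0.245 (95% interval -0.762 to 0.846, permutation p = 0.492) and Spearman's rho was -0.188 (permutation p = 0.608), and r was 0.414 without the 2 farthest libraries. With days on doxycycline r was -0.34 (95% interval -0.891 to 0.506, permutation p = 0.329) and rho was -0.181 (permutation p = 0.614), and r was -0.563 without the 2 farthest libraries. Adjusted over the 2 relations computed, both p for r were 0.492 and both p for rho 0.614. Intervals this wide leave both hypotheses open, and days reach 49 only with GSK2830371.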
